A study of Mus musculus with 7 samples.

How the data were processed

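Nuclei were isolated from flash-frozen striatum through lysis buffer and an iodixanol density barrier and made into libraries with the Chromium Single Cell 3' kit, version 3 chemistry, per the labels' protocols. Libraries from 3 WT and 4 HttQ175/+ mice were used, 1 per mouse. Reads were processed with Cell Ranger 3.0.2 and Seurat on the mm10 build, per the submitters' processing notes. Filters on nuclei, the calling of cell types and the use of strand in counting are not given in the sources used here. The authors deposited a table per mouse on a natural log scale, in which each value is the natural log of 1 plus UMIs per 10000 UMIs of the nucleus, over 27998 genes. The linear values of every nucleus summed to 10000. Whole UMIs were recovered from the smallest step in each nucleus, and 100% of the 5824756 values above 0 were whole UMIs within a tolerance of 0.02. The other deposited table used here, with other columns such as the cell type, library and genotype of each nucleus, is the authors' annotation; its genotypes matched the labels in all 4524 nuclei. A table of values smoothed across nuclei was not used, because smoothing shares values between nuclei.

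Nuclei held 1128 to 5632 UMIs, at least 636 genes and at most 4.992% mitochondrial UMIs. Median UMIs per nucleus were 2498, 2599 and 2561 in WT replicates 1 to 3 and 2262, 1657, 2385 and 1991 in HttQ175/+ replicates 1 to 4. No nuclei were left out of the main comparisons. Scrublet in scanpy 1.11.5 marked 40 nuclei or 0.884% as doublets, with a threshold of its own in each mouse, so its counts are not comparable between mice. Whether doublets had been removed before deposit is not given in the sources used here.

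The test planned before the data were examined was one for counts; because the deposited unit is a natural log and not a count, limma 3.58.1 in R 4.3.3 was used instead of edgeR. For each mouse and type the linear values were averaged over nuclei, expressed as CPM, scaled by trimmed means of M values (TMM), and taken as log2 of CPM plus a pseudocount worth 2 UMIs of the median mouse. The pseudocount was 3.67 CPM in dSPNs, 8.31 in iSPNs, 22.7 in astrocytes, 15.06 in oligodendrocytes and 22.47 in Sst interneurons, and it makes fold changes of low genes smaller. Genes entered with at least 15 UMIs in all and at least 10 at the median sum in 3 mice or more. limma-trend gave moderated tests of HttQ175/+ against WT with Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Mean CPM are printed before TMM scaling, so their ratios differ from the fitted changes by the scaling. A type was tested with at least 10 nuclei in at least 3 mice per genotype, which microglia and oligodendrocyte progenitors did not reach. Sst interneurons stood for the interneurons. The difference between dSPNs and iSPNs was fitted with the mouse as a block. All mice were male and of 1 strain, so no covariate was used. The labels give no numbers that pair mice across genotypes.

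Genes were named by a rule set before the data were examined. Among genes past the threshold whose HttQ175/+ mice all lay on 1 side of all WT mice, and with a mean of at least 20 CPM, the 12 largest rises and 12 largest falls were named in dSPNs and iSPNs, and the 5 largest of each in other types. For the test of the difference, the 5 genes of each direction with the smallest p were to be named. Up to 4 passing members of each list, and Htt in every tested type, were added. Where nothing passed, the 3 genes with the smallest p were named as not passing. Genes with provisional names were counted and not named, and a few genes that meet the rule are not reported here. Coordinates are from the GENCODE vM21 annotation of mm10.

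Gene lists were fixed before the data were examined and tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the 54 pairs of list and type with at least 3 members. Of these 54 pairs 20 passed; 13 passed with fry and 2, the SPN identity genes in dSPNs and iSPNs, with an estimated correlation. Lists of SPN identity, dSPN identity, iSPN identity, developmental transcription factors, cholesterol synthesis, immediate early genes, postsynapse, potassium channels, cyclic nucleotide signalling, heat shock, DNA repair, p53, oxidative phosphorylation, protocadherins, mitochondrially encoded genes and ribosomal proteins were tested in neurons, glia or both, and myelin, immature oligodendrocyte and homeostatic astrocyte lists in their own type. Lists for reactive astrocytes and interferon had too few measured members to test in any type. Those for microglia were not tested, because microglia held too few nuclei. Type-enriched genes were ranked by log2 CPM with 20 CPM added. Shares of nuclei and depth were compared with an exact two-sided permutation test over the 35 splits of 7 mice. The 95% counting intervals, from scipy 1.17.1, and floors of 3 UMIs cover counting error only.

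The fits were tested on simulated data with 200 changed genes. In each single type the simulated spread between mice was 0.25 on the log2 scale and was not matched to the data. The 200 genes are a larger part of the genes in small types, so the rates do not rank the types. Of genes changed 2-fold and 4-fold, 55.2% and 96.7% were recovered in dSPNs (8817 genes), 42.9% and 96.5% in iSPNs (5975 genes), 59.0% and 96.0% in astrocytes (1722 genes), 41.3% and 94.4% in oligodendrocytes (3618 genes) and 47.9% and 94.7% in Sst interneurons (2207 genes). The test of the difference recovered 37.8% and 97.6% (6093 genes). Alternatives planned before the data were examined were other scaling factors, no filter, nuclei with at most 1% mitochondrial UMIs and no doublet mark, equal numbers of nuclei, a minimum of 30 nuclei, a limit of 0.5 on the log2 change, other list tests, other choices of enriched genes and leaving out each mouse. Pseudocounts worth 0.5 and 5 UMIs, no scaling, recovered UMI sums, voom weights, nuclei thinned to 1500 UMIs, SPNs as 1 class and leaving out HttQ175/+ replicates 2 and 4 were added after the data were seen.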

Results

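Nuclear RNA of single nuclei was measured in the striatum of 7 male C57BL6/J mice. Of these, 3 were wild type (WT) and 4 carried HttQ175, a knock-in allele of the mouse huntingtin gene with an expanded CAG repeat that models Huntington's disease, in 1 copy (HttQ175/+). The mice were 14 months old except HttQ175/+ replicate 1, which was 15 months old. Each mouse gave 1 droplet library read from the 3' ends of transcripts, so the mouse is the replicate, and replicate numbers only name mice. The series asked whether the mutation alters the identity of striatal cell types. The deposited annotation placed 4524 nuclei in 12 types, among them the spiny projection neurons (SPNs) of the direct pathway (dSPNs) and of the indirect pathway (iSPNs), the main output neurons of the striatum. WT replicates 1, 2 and 3 held 418, 338 and 558 nuclei with 1049731, 872558 and 1436425 unique molecular identifiers (UMIs) in all. HttQ175/+ replicates 1, 2, 3 and 4 held 822, 1239, 448 and 701 nuclei with 1994564, 2256178, 1096116 and 1547681 UMIs. Enough nuclei for a test between genotypes were present for dSPNs, iSPNs, astrocytes, oligodendrocytes and Sst interneurons. Changes are given as log2 fold changes of HttQ175/+ over WT ± SE from limma with Benjamini-Hochberg adjustment over the genes of a type, and levels are mean CPM ± SD over 3 WT and 4 HttQ175/+ mice.

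Huntingtin itself (Htt; chromosome 5, 34761740 to 34912534, mm10) passed the test in none of the 5 types. In dSPNs Htt stood at 188.1 ± 11.3 CPM in WT and 172.0 ± 34 CPM in HttQ175/+ mice, a log2 change of -0.28 ± 0.18 (adjusted p = 0.461). The change of Htt was -0.13 ± 0.21 in iSPNs, 0.18 ± 0.35 in astrocytes, 0.01 ± 0.30 in oligodendrocytes and -0.64 ± 0.26 in Sst interneurons, with adjusted p of 0.832, 0.858, 0.998 and 0.627. In Sst interneurons Htt lay lower in all 4 HttQ175/+ mice (175.4 to 254.8 CPM) than in all 3 WT mice (322.5 to 349.6 CPM). These 3' tags lie far from the CAG repeat at the other end of the gene, so they do not check which mice carry the knock-in allele.

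The first comparison asked which genes differ by genotype in dSPNs. Genes that mark SPNs fell together. Pde10a, a phosphodiesterase abundant in SPNs (chromosome 17, 8525372 to 8986648), stood at 3975 ± 44.3 CPM in WT and 1689 ± 28.9 CPM in HttQ175/+ mice, a log2 change of -1.37 ± 0.10. Scn4b, a sodium channel beta subunit (chromosome 9, 45138395 to 45154152), went from 548.1 ± 37.4 to 150.7 ± 56.2 CPM (-2.06 ± 0.26). Cnr1, the CB1 cannabinoid receptor (chromosome 4, 33924593 to 33948831), went from 612.8 ± 108.5 to 165.3 ± 31.7 CPM (-2.01 ± 0.19). Ryr1, an intracellular calcium release channel (chromosome 7, 29003344 to 29125179), fell from 257.9 ± 7.30 to 33.8 ± 13.2 CPM (-3.0 ± 0.24). In the other direction Vwa5b2 (chromosome 16, 20589471 to 20605377) rose from 11.9 ± 4.45 to 115.5 ± 19.2 CPM, a log2 change of 2.85 ± 0.25. The adjusted p of these 5 genes ran from 1.82e-05 for Pde10a to 0.000537 for Scn4b. Of 8790 genes tested in dSPNs, 120 rose and 229 fell at an adjusted p under 0.05.

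Other large falls in dSPNs included that of Abi3bp. This extracellular matrix protein fell by 2.90 ± 0.26 (adjusted p = 4.54e-05), from 90.1 to 10.1 CPM. Car12, a membrane carbonic anhydrase (-2.34 ± 0.23), and Cd59a, an inhibitor of complement (-2.12 ± 0.31), fell with adjusted p of 4.77e-05 and 0.00137. Clec12a, a lectin receptor, fell by 1.89 ± 0.33 (adjusted p = 0.00465). Tbc1d4, a regulator of vesicle traffic, had a log2 change of -1.87 ± 0.23, Rcn1, a calcium-binding protein of the endoplasmic reticulum, one of -1.85 ± 0.36, and the adaptor Dok3 one of -1.85 ± 0.49 (adjusted p = 0.000518, 0.00868 and 0.0487). Penk, the enkephalin precursor that marks iSPNs, was read in dSPN nuclei at 89.0 CPM in WT and 26.4 CPM in HttQ175/+ mice (-1.86 ± 0.34, adjusted p = 0.00619). These levels lie below those of 258.3 and 102.0 CPM in oligodendrocytes, which should lack Penk, so they are at background and do not show expression in dSPNs. The non-coding Abhd11os, which is antisense to Abhd11, fell by 2.45 ± 0.40 (adjusted p = 0.00324); the use of strand in counting is not given in the sources used here, so this value is uncertain.

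Sfmbt2, a Polycomb group protein (chromosome 2, 10370510 to 10595253), and the neurite growth factor Nrn1 were nearly absent from WT dSPNs. Sfmbt2 had 1 UMI in WT and 118 UMIs in HttQ175/+ dSPNs, a ratio of 59.5 per UMI sequenced with a 95% counting interval from 10.5 to 2368.7, and Nrn1 had 1 and 102 UMIs, a ratio of 51.4 with an interval from 9.0 to 2050.2. Their fitted changes of 3.35 ± 0.37 and 3.01 ± 0.42 (adjusted p = 0.000199 and 0.00119) depend on the pseudocount. Further rises were 2.59 ± 0.38 for the lipid transporter Abca7, 2.39 ± 0.45 for the calcium/calmodulin kinase Camk2d, 2.23 ± 0.28 for the collagen Col11a1 and 2.15 ± 0.36 for the centrosomal protein Cntrl. Cers2, a ceramide synthase, rose by 2.14 ± 0.32 and the long non-coding RNA Miat by 1.76 ± 0.24, from 39.3 to 154.9 CPM. Kndc1, the protocadherin Pcdhb21 and the heparan sulfate enzyme Ndst3 completed the 12, with 1.67 ± 0.29, 1.67 ± 0.41 and 1.66 ± 0.34. Adjusted p of these genes lay between 0.000553 for Col11a1 and 0.0351 for Pcdhb21.

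By list, the SPN identity genes of dSPNs fell. Of 30 measured, 22 fell and 0 rose over all genes tested, 27 fell adjusted over the list alone, and the median log2 change was -0.89 (camera in limma, adjusted p = 3.65e-30, and adjusted p = 0.0203 with an estimated correlation). In the same nuclei summed markers stood higher in all 4 HttQ175/+ than in all WT mice for neural progenitors and neuroblasts (70.5 ± 9.9 and 123.5 ± 23.3 CPM), eccentric SPNs (85.6 ± 12.8 and 126.9 ± 17.9 CPM, where Col11a1 passed), cortical excitatory neurons (6.8 ± 3.5 and 27.5 ± 9.3 CPM, where Neurod2 passed) and macrophages and other immune cells (1.3 ± 1.4 and 6.3 ± 4.1 CPM). Of the 3 eccentric SPN markers tested 1 rose, Col11a1 (from 8.08 to 55.1 CPM), and the median log2 change of the 3 was 0.03. The higher eccentric SPN sum was thus that of Col11a1 and not of the set. Of the interneuron markers 1 could be tested, Elavl2, which rose by 1.17 ± 0.23 (adjusted p = 0.00932). Neurod2 and Elavl2 were picked after their values were seen. Changes were -1.48 ± 0.14 for Adcy5, the main adenylyl cyclase of SPNs, and -1.41 ± 0.16 for Pde1b, a calmodulin-dependent phosphodiesterase (adjusted p = 4.77e-05 and 0.000293). Of the 11 dSPN identity genes 4 fell, both over all genes and adjusted over the list alone, where 1 also rose; the median was -0.31 (adjusted p = 0.0118, but adjusted p = 0.207 with an estimated correlation). Those 4 were the precursor of substance P, Tac1 (-1.09 ± 0.16, from 487.3 to 248.3 CPM), the dynorphin precursor Pdyn (-1.06 ± 0.25), the mitochondrial serine carrier Sfxn1 (-0.79 ± 0.18) and the dopamine receptor Drd1 (-0.75 ± 0.19, from 471.0 to 305.5 CPM), with adjusted p of 0.00164, 0.0253, 0.0211 and 0.0345. Of 19 cyclic nucleotide signalling genes 5 fell and 0 rose (7 and 1 adjusted over the list alone; median -0.19, adjusted p = 0.00196, but adjusted p = 0.269 with an estimated correlation). Pde10a, Adcy5, Pde1b and Pde2a (-0.79 ± 0.18, adjusted p = 0.0191) led this list, and all 4 are also SPN identity genes.

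Genes of the glutamatergic postsynapse went both ways in dSPNs. Of 23 measured 1 rose and 6 fell (1 and 7 adjusted over the list alone), with a median of -0.18 (adjusted p = 0.00221, but adjusted p = 0.283 with an estimated correlation). Shank1, a scaffold of the postsynaptic density, rose by 1.12 ± 0.23 (adjusted p = 0.0129). Falls were -1.38 ± 0.29 for the metabotropic receptor Grm3, -0.99 ± 0.14 for the kinase subunit Camk2b and -0.89 ± 0.14 for the kainate receptor Grik2 (adjusted p = 0.0125, 0.00119 and 0.00202). Of 23 potassium channel genes 2 fell (6 adjusted over the list alone; median -0.15, adjusted p = 0.00506, but adjusted p = 0.207 with an estimated correlation), namely Kcnh4 (-1.15 ± 0.20, adjusted p = 0.00463) and Kcnk2 (-0.85 ± 0.18, adjusted p = 0.0152). Of 16 clustered protocadherins, adhesion proteins of neurons, 5 rose over all genes and 9 adjusted over the list alone, with a median of 0.79 (adjusted p = 0.000102, but adjusted p = 0.231 with an estimated correlation). All 5 belonged to the beta cluster (Pcdhb genes), and no gamma member passed. Among gamma members Pcdhga6, Pcdhga9, Pcdhga12 and Pcdhgc5 lay at -0.43, -0.35, -0.18 and -0.18. The gamma members Pcdhgb4 and Pcdhgb5 lay at 0.16 and 0.74. Pcdhb19 rose by 1.51 ± 0.30, Pcdhb20 by 1.35 ± 0.28 and Pcdhb14 (chromosome 18, 37447656 to 37456350) by 1.13 ± 0.18 (adjusted p = 0.00981, 0.0136 and 0.00293). Protocadherin genes are alike in sequence, so values of single members are uncertain.

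Of the developmental transcription factors that Polycomb represses in most tissues, 3 could be tested in dSPNs, and the list did not pass (1 rose over all genes and 2 adjusted over the list alone; median 0.47, adjusted p = 0.0728). Shox2, a homeobox factor, rose from 0 UMIs in WT to 63 UMIs in HttQ175/+ mice (adjusted p = 0.00144). Against a floor of 3 UMIs over the WT mice it was at least 10.6-fold higher. The median of the list, 0.47 for Onecut2, stayed the same with Shox2 at that bound. Lists that did not pass in dSPNs were the iSPN identity genes (median -0.24, adjusted p = 0.357), immediate early genes (-0.19, 0.154), heat shock genes (0.07, 0.830), DNA repair modifiers of Huntington's disease (0.02, 0.693) and p53 genes (0.13, 0.774). The mitochondrially encoded (-0.45, 0.167) and ribosomal protein genes (-0.11, 0.343) did not pass either. Ribosomal protein genes have many pseudogenes, so the single calls Rps28 (1.56 ± 0.38), Rps13 (-0.89 ± 0.22) and Rps6 (-1.17 ± 0.31) are uncertain (adjusted p = 0.0340, 0.0343 and 0.0498). Cholesterol synthesis genes had a median of 0.00 and a mean of -0.01 but an upward camera test (adjusted p = 0.995), and oxidative phosphorylation genes a median of -0.07 against a mean of 0.04 and an upward test (adjusted p = 0.980), so their signs differed.

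The dSPN fit held 119 to 509 nuclei and 334640 to 906138 UMIs per mouse. All HttQ175/+ mice lay beyond all WT mice for 1429 genes or 16.3%, where chance gives 5.7%, and for 345 of the 349 genes that passed. Scaling by trimmed means moved the median of all dSPN genes from 0.14 to 0.01, and changes are given relative to it. Without that scaling 223 genes rose and 161 fell, so the share of falls was 41.9% in place of 65.6%, and no gene named here turned sign. Without HttQ175/+ replicate 1, the 15-month mouse, the count of genes that passed was 208. Of 45 genes named as called, 32 passed with any 1 mouse left out, and Grm3, Shank1, Kcnk2, Pcdhb20, Pde2a, Pdyn, Drd1, Rps13, Sfxn1, Dok3, Pcdhb21, Rps28 and Rps6 did not in 1 to 6 of the 7 cases (highest adjusted p from 0.0514 for Shank1 to 0.147 for Rps6).

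**Figure D1:**
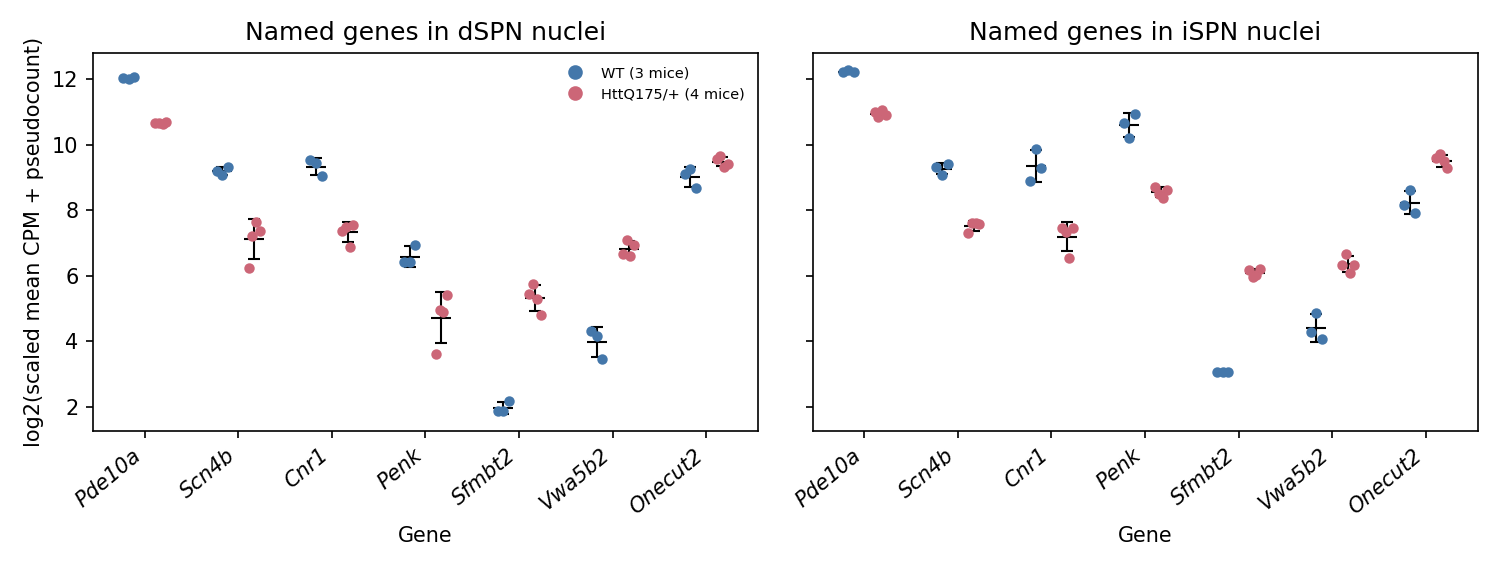
Levels of 7 genes in dSPN nuclei (left) and iSPN nuclei (right), as log2 of the scaled mean CPM plus the pseudocount, with 1 dot per mouse, WT in blue and HttQ175/+ in red, and bars for the mean and SD. Pde10a, Scn4b, Cnr1 and Penk lie lower, and Sfmbt2 and Vwa5b2 higher, in all 4 HttQ175/+ mice than in all 3 WT mice in both types; Onecut2 does so too, with log2 changes of 0.47 in dSPNs, which did not pass the test, and 1.29 in iSPNs, which did.

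The same comparison in iSPNs again found lower levels of genes that mark the type. Penk (chromosome 4, 4133531 to 4138819), the transmitter precursor of iSPNs, fell from 1498 ± 338.3 to 381.3 ± 39.9 CPM, a log2 change of -2.05 ± 0.18 (adjusted p = 1.52e-05). Pde10a fell from 4575 ± 174.2 to 2041 ± 114.8 CPM (-1.28 ± 0.11), Cnr1 from 640.5 ± 229.6 to 148.3 ± 40.9 CPM (-2.16 ± 0.26) and Scn4b from 580.8 ± 57.6 to 182.5 ± 19.4 CPM (-1.75 ± 0.18). Arpp19, a regulator of protein phosphatase activity, fell from 645.0 to 167.4 CPM (-2.03 ± 0.19). The homeobox factor Onecut2 (chromosome 18, 64340020 to 64400987) rose from 284.3 ± 77.0 to 755.0 ± 97.2 CPM, a log2 change of 1.29 ± 0.19. Adjusted p of these genes were at most 0.00166. Of 5894 genes tested, 31 rose and 110 fell.

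Sfmbt2 had 0 UMIs in WT iSPNs and 74 UMIs in HttQ175/+ iSPNs, where it averaged 62.5 ± 5.79 CPM. Against the floor of 3 UMIs over the WT mice it was at least 17.8-fold higher (adjusted p = 0.00166), and its fitted change of 3.04 ± 0.46 depends on the pseudocount. Vwa5b2 rose by 1.94 ± 0.32 and Ece2, a peptidase encoded next to it (chromosome 16, 20629828 to 20646485), by 1.70 ± 0.24, with adjusted p of 0.00298 and 0.00106. Shank1 rose by 1.49 ± 0.23 (adjusted p = 0.00166). Smaller rises were those of the kinesin adaptor Fez1 (1.40 ± 0.34), the glycosyltransferase Mgat4c (1.26 ± 0.26), the matrix protein Edil3 (1.23 ± 0.30) and the endocytosis protein Pacsin1 (1.12 ± 0.22). Genes that fell were Abi3bp (-2.35 ± 0.40), Tbc1d4 (-1.93 ± 0.33), the nuclear protein Ptma (-1.92 ± 0.31), the carbonic anhydrase relative Car11 (-1.69 ± 0.35) and Upb1, an enzyme of pyrimidine breakdown (-1.66 ± 0.35). The matrix proteoglycan Spock3 (-1.56 ± 0.24), the calcium sensor Hpca (-1.55 ± 0.21) and the BDNF receptor Ntrk2 (-1.53 ± 0.26) fell as well. Adjusted p of these 12 rises and falls ran from 0.00106 for Hpca to 0.0399 for Edil3.

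In iSPNs 16 of 29 SPN identity genes fell and 0 rose (24 fell adjusted over the list alone), with a median of -0.89 (adjusted p = 7.85e-26, and adjusted p = 0.0301 with an estimated correlation). Summed markers of eccentric SPNs stood at 40.3 ± 5.6 CPM in WT and 91.5 ± 17.9 CPM in HttQ175/+ iSPNs, and those of neural progenitors and neuroblasts at 84.6 ± 19.2 and 132.7 ± 18.8 CPM, both higher in all 4 HttQ175/+ mice than in all WT mice. Only 1 eccentric SPN marker could be tested in iSPNs. Its log2 change was 1.91 but it was not called, so a rise of that set is not shown. Adcy5 changed by -1.34 ± 0.16 and Pde1b by -1.28 ± 0.19 (adjusted p = 0.000291 and 0.00166). Of 8 iSPN identity genes 4 fell (5 adjusted over the list alone; median -0.83, adjusted p = 0.000157, but adjusted p = 0.207 with an estimated correlation). Besides Penk and Upb1 these were the adenosine receptor Adora2a (-1.02 ± 0.17, from 502.6 to 265.7 CPM) and the orphan receptor Gpr6 (-1.25 ± 0.23), with adjusted p of 0.00375 and 0.00769. Of 18 cyclic nucleotide genes 4 fell (5 adjusted over the list alone; median -0.07, adjusted p = 0.0116, but adjusted p = 0.231 with an estimated correlation), among them the protein kinase A subunit Prkar2b (-0.81 ± 0.21, adjusted p = 0.0489). Of 7 protocadherins 3 rose over all genes and 4 adjusted over the list alone (median 0.96, adjusted p = 0.00282, but adjusted p = 0.207 with an estimated correlation). All 4 belonged to the beta cluster, while the gamma members Pcdhgc5 and Pcdhga12 lay at -0.49 and -0.29. Pcdhb19 rose by 1.57 ± 0.38, Pcdhb17 by 1.34 ± 0.33 and Pcdhb14 by 0.96 ± 0.24 (adjusted p = 0.0399, 0.0405 and 0.0492).

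Other lists did not pass in iSPNs. Postsynaptic genes had a median of -0.23 (adjusted p = 0.167), although Camk2b fell by 0.92 ± 0.16 (adjusted p = 0.00375), and potassium channels one of -0.02 (adjusted p = 0.301), although Kcnh4 fell by 1.05 ± 0.23 (adjusted p = 0.0178). Medians and adjusted p were -0.15 and 0.613 for cholesterol synthesis, -0.33 and 0.677 for immediate early genes, 0.44 and 0.120 for DNA repair modifiers, -0.12 and 0.457 for p53 genes, -0.08 and 0.357 for oxidative phosphorylation, -0.20 and 0.203 for mitochondrially encoded genes and -0.09 and 0.540 for ribosomal proteins. Signs differed for the dSPN identity genes (median 0.18, mean -0.12, downward test, adjusted p = 0.693) and heat shock genes (median -0.07, mean 0.04, upward test, adjusted p = 0.613). The fit held 78 to 264 nuclei and 209301 to 433227 UMIs per mouse, and 804 genes or 13.6% were separated by genotype against 5.7% by chance. The count of 141 genes fell to 65 without WT replicate 1, 86 without WT replicate 3, 82 without HttQ175/+ replicate 1 and 91 without HttQ175/+ replicate 2. With 1 mouse left out, Prkar2b lost its call in all 7 cases. Edil3, Fez1, Pcdhb14 and Pcdhb17 lost theirs in 6 of 7, Kcnh4 in 5 of 7 and Pcdhb19 in 5 of 6. Pacsin1, Upb1, Car11 and Mgat4c lost theirs in 1 to 3 of 7. The highest adjusted p by limma ran from 0.0546 for Pacsin1 to 0.166 for Pcdhb14. Without scaling, which moved the median of all iSPN genes from 0.10 to -0.01, 43 genes rose and 74 fell, a share of falls of 63.2% in place of 78.0%.

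Whether the genotype effect differs between dSPNs and iSPNs was tested directly, with the mouse as a block. Effects in the 2 types went together: over 5887 genes tested in both, 16 rose in both and 79 fell in both, where independent lists would share 0.35 and 3.5, and 0 went opposite ways. The log2 changes correlated across genes with a Pearson r of 0.634 and a Spearman rho of 0.549, and genes are not independent replicates. Because both types come from the same mice, chance values are shared. Over the other 34 ways to split the mice the median r was 0.388 and the highest 0.594. The covariance was 0.103 against a median of 0.0339 and a highest of 0.0757. Both highest values came from the split of HttQ175/+ replicates 1, 2 and 4 against the rest. Such splits hold part of the genotype effect, so they give no clean chance level. The 3 WT mice cannot be halved, so part of the excess may come from shared controls. The direct test called 0 of 5887 genes by limma, with 388 at an unadjusted p under 0.05. Its smallest p were those of Onecut2, whose change was 0.47 in dSPNs and 1.29 in iSPNs (difference 0.78 ± 0.15, adjusted p = 0.0522), and the ribosomal protein gene Rpl37 (0.91 and -1.32; difference -2.25 ± 0.44, adjusted p = 0.0522), and neither passed. Single settings moved this count: 1 gene passed without WT replicate 2 (Onecut2) or without HttQ175/+ replicate 2 (Rpl37), and 3, among them Ryr1 and Rpl37, without HttQ175/+ replicate 3.

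**Figure D2:**
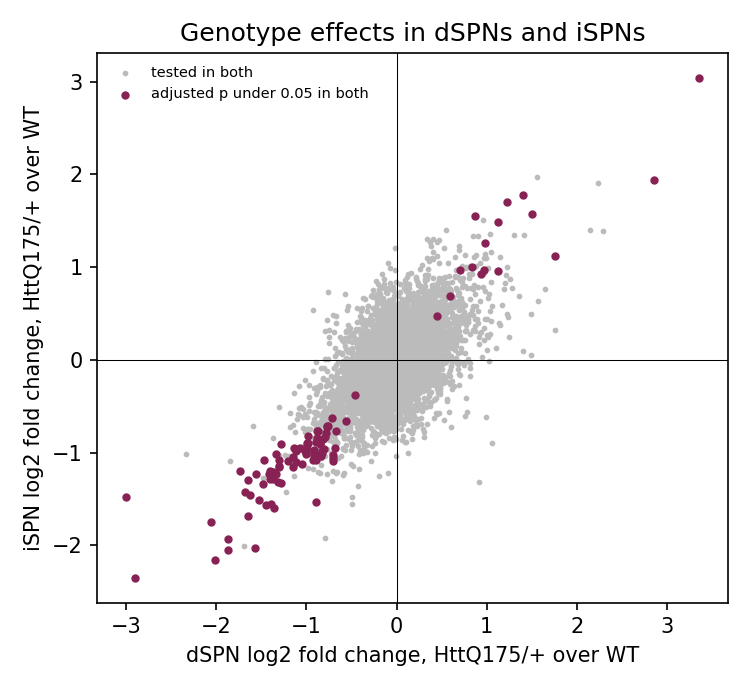
Log2 fold changes of HttQ175/+ over WT in dSPNs (horizontal) and iSPNs (vertical), with 1 dot per gene for the 5887 genes tested in both types. The 95 genes that passed in both types, in purple, lie in the lower left (79) or the upper right (16).

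The next comparison asked whether genes that set a type apart from the other types move with genotype. For each type the 200 most enriched genes were taken, with both genotypes weighted equally; they were chosen on these samples and are not independent evidence of a direction. In iSPNs 156 of the 200 lay below 0 (median -0.30; 27 fell and 1 rose; camera adjusted p = 2.90e-12, and adjusted p = 0.00587 with an estimated correlation). In dSPNs 135 did (median -0.23; 22 fell and 1 rose; adjusted p = 1.57e-06, and adjusted p = 0.0143 with an estimated correlation). Astrocyte-enriched genes had a median of -0.61 with 184 below 0 and 0 called singly (adjusted p = 2.69e-29, and adjusted p = 0.0456 with an estimated correlation). Oligodendrocyte-enriched genes had a median of -0.67 with 181 below 0 and 12 that fell (adjusted p = 3.01e-40, but adjusted p = 0.0914 with an estimated correlation). Genes enriched in Sst interneurons had a median of -0.13 with 118 below 0 and 0 called (adjusted p = 0.0240, but adjusted p = 0.150 with an estimated correlation). That last call was lost without WT replicate 1, HttQ175/+ replicate 1 or HttQ175/+ replicate 2 (adjusted p = 0.239, 0.141 and 0.0538).

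In oligodendrocytes, the myelinating glia, 25 genes passed the test. Glul, glutamine synthetase (chromosome 1, 153899944 to 153909723), fell from 1067 ± 174.3 to 217.4 ± 64.5 CPM, a log2 change of -2.35 ± 0.28 (adjusted p = 0.000148). Sgk1, a kinase regulated by glucocorticoids, fell by 2.00 ± 0.31 (adjusted p = 0.00370). The small GTPase Rhog (-1.77 ± 0.33), Mettl7a1 (-1.69 ± 0.39) and the growth cone protein Dpysl2 (-1.68 ± 0.38) fell too (adjusted p = 0.0112, 0.0448 and 0.0411). The cyclin-dependent kinase Cdk17 rose by 1.73 ± 0.37 and the chromatin remodeller subunit Smarcd1 by 1.52 ± 0.36 (adjusted p = 0.0276 and 0.0471). All 25 measured genes of mature oligodendrocytes and myelin lay below 0, 8 fell over all genes tested and 20 fell adjusted over the list alone, with a median of -1.05 (adjusted p = 3.98e-23, but adjusted p = 0.231 with an estimated correlation, which was 0.71 between these genes). The myelin genes Mobp (chromosome 9, 120149707 to 120181484) and Mal (chromosome 2, 127633226 to 127656695) changed by -1.65 ± 0.34 and -1.57 ± 0.28, the tight junction protein Cldn11 by -1.55 ± 0.31 and the carbonic anhydrase Car2 by -1.54 ± 0.27 (adjusted p = 0.0205, 0.00788, 0.0155 and 0.00788). Over 3641 genes, 2 rose and 23 fell.

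Transcripts of SPNs and mitochondrial RNA also differed on average between genotypes in the same oligodendrocyte nuclei. Summed SPN markers stood at 4439 ± 451.8 CPM in WT and 3368 ± 781.8 CPM in HttQ175/+ oligodendrocytes. As SPN markers fell by a larger factor in SPNs themselves, SPN identity genes stood at 35.5% ± 5.3 of their SPN level in WT and at 49.2% ± 14.0 in HttQ175/+ oligodendrocytes. Summed markers of neural progenitors and neuroblasts stood at 46.4 ± 24.6 and 106.7 ± 11.1 CPM. Those of macrophages and other immune cells stood at 1.9 ± 3.3 and 20.9 ± 13.4 CPM. Both sums were higher in all HttQ175/+ mice than in all WT mice. The 8 mitochondrially encoded genes tested all lay below 0 (0 called over all genes and 5 adjusted over the list alone; median -0.69, adjusted p = 0.000157, but adjusted p = 0.348 with an estimated correlation). The heat shock list had a median of -0.50 with 1 fall over all genes and 3 adjusted over the list alone (adjusted p = 0.00935, but adjusted p = 0.355 with an estimated correlation). That gene was Cryab, a small heat shock protein, which fell by 1.32 ± 0.29 (adjusted p = 0.0340). Ribosomal protein genes had a median of -0.28 (adjusted p = 0.00282, but adjusted p = 0.445 with an estimated correlation). Lists that did not pass were immediate early genes (median 0.48, adjusted p = 0.645), p53 genes (-0.20, 0.693), oxidative phosphorylation (-0.30, 0.145) and immature oligodendrocyte genes, whose median of -0.00 differed in sign from the mean of 0.25 and the upward test (adjusted p = 0.674).

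The oligodendrocyte fit held 32 to 109 nuclei and 77673 to 260976 UMIs per mouse, and 399 genes or 11% were separated by genotype against 5.7% by chance. The count of 25 genes rested on few libraries. It was 7, 4 and 1 without WT replicates 1, 2 and 3, and 14, 16, 133 and 13 without HttQ175/+ replicates 1, 2, 3 and 4. Of the 12 genes named as called, Glul alone passed with any 1 mouse left out (highest adjusted p = 0.0114). HttQ175/+ replicate 3 had the highest level of Cldn11, Mobp, Mal, Car2 and Glul among the HttQ175/+ mice.

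**Figure D3:**
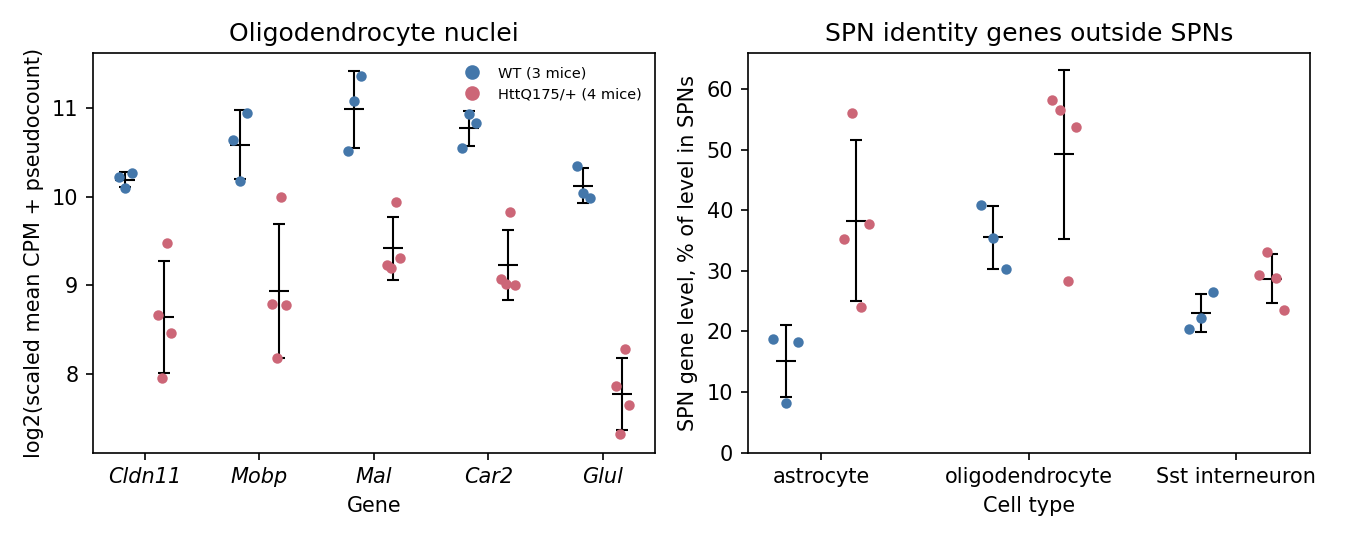
Left, expression of 5 genes in oligodendrocyte nuclei as log2 of the scaled mean CPM plus the pseudocount; right, the level of SPN identity genes in 3 other types as a percentage of their level in SPNs, with 1 dot per mouse and bars for the mean and SD. All 5 genes lie lower in all 4 HttQ175/+ mice, and the SPN gene level in oligodendrocytes runs from 30.3% to 40.8% in WT and from 28.4% to 58.2% in HttQ175/+ mice.

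In astrocytes, which clear glutamate and potassium, 0 of 1858 genes passed by limma; 263 had an unadjusted p under 0.05, and voom weights called 20. The smallest p, none of which passed (adjusted p = 0.0812 each), were those of the growth factor Vegfa at 1348 CPM in WT and 575.7 CPM in HttQ175/+ mice (-1.30 ± 0.28), the long non-coding RNA Meg3 at 2680 and 8561 CPM (1.53 ± 0.34), and the kinase Dclk1 at 3445 and 1780 CPM (-1.09 ± 0.24). Of 22 homeostatic astrocyte genes 20 lay below 0, 0 were called over all genes and 6 fell adjusted over the list alone (median -0.48, adjusted p = 9.74e-05, but adjusted p = 0.348 with an estimated correlation). SPN identity genes stood at 15.1% ± 6.0 of their SPN level in WT astrocytes and at 38.3% ± 13.3 in HttQ175/+ astrocytes, and summed SPN markers at 2098 ± 823.8 and 2509 ± 799.3 CPM. In the same nuclei summed oligodendrocyte markers stood at 835.8 ± 260 and 1512 ± 503.5 CPM, and microglial markers at 64.4 ± 32.5 and 262.3 ± 157.5 CPM, with all 4 HttQ175/+ mice above all WT mice for microglial markers. Summed dSPN markers (279.7 ± 35.9 and 415.3 ± 65 CPM) and cholinergic interneuron markers (7.1 ± 7.1 and 57.2 ± 52.4 CPM) were also higher in all 4 HttQ175/+ mice. Ribosomal protein genes, all 10 above 0, had a median of 0.82 (adjusted p = 0.00506, but adjusted p = 0.207 with an estimated correlation). Heat shock genes had a median of 0.88 (1 rose adjusted over the list alone; adjusted p = 0.00385, but adjusted p = 0.207 with an estimated correlation), and mitochondrially encoded genes one of 0.33 (adjusted p = 0.00882, but adjusted p = 0.414 with an estimated correlation). Oxidative phosphorylation (median 0.38, adjusted p = 0.0659) and cholesterol synthesis (-0.64, 0.211) did not pass. The fit held 26 to 71 nuclei and 40870 to 153668 UMIs per mouse, 248 genes or 13.3% were separated by genotype against 5.7% by chance, and 11 genes passed without HttQ175/+ replicate 3.

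In Sst interneurons 0 of 2233 genes passed by limma and 0 with voom weights, and 163 had an unadjusted p under 0.05. The smallest p, none of which passed (adjusted p = 0.272 each), were those of Penk at 223.2 and 33.3 CPM (-2.18 ± 0.47), the lysosomal glucosidase Gaa at 323.8 and 110.2 CPM (-1.39 ± 0.31) and the SPN gene Rgs9 at 331.5 and 139.2 CPM (-1.17 ± 0.28). SPN identity genes were read here too, at 23.0% ± 3.1 of their SPN level in WT and 28.7% ± 4.0 in HttQ175/+ mice. Summed microglial markers stood at 22.8 ± 20.4 and 71.4 ± 21.0 CPM, and astrocyte markers at 112.7 ± 47.0 and 272.6 ± 192.2 CPM. Both were higher in all 4 HttQ175/+ mice than in all WT mice. Summed SPN markers (2720 ± 433.5 and 1871 ± 480.6 CPM) and iSPN markers (447.7 ± 102.0 and 174.0 ± 55.1 CPM) were lower in all 4 HttQ175/+ mice. Of 12 SPN identity genes tested 11 lay below 0, 0 were called over all genes and 1 fell adjusted over the list alone. Their median was -0.62 (camera adjusted p = 0.000171, but adjusted p = 0.207 with an estimated correlation). The 4 mitochondrially encoded genes had a median of 0.91 (adjusted p = 0.00170, but adjusted p = 0.231 with an estimated correlation). Medians and adjusted p of the lists that did not pass were -0.30 and 0.357 for dSPN identity, -0.17 and 0.203 for the postsynapse, 0.27 and 0.204 for potassium channels, -0.07 and 0.204 for cyclic nucleotides, -0.06 and 0.980 for heat shock and -0.15 and 0.613 for oxidative phosphorylation. Ribosomal protein genes had a median of 0.00, a mean of -0.09 and a downward test (adjusted p = 0.875). The fit held 18 to 68 nuclei and 42074 to 152312 UMIs per mouse, and 181 genes or 8.1% were separated by genotype against 5.7% by chance.

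The share of each type among a mouse's nuclei was compared by an exact two-sided permutation test. The share of iSPNs was 24.9% ± 3.16 (SD, n = 3) in WT and 18.8% ± 2.64 (SD, n = 4) in HttQ175/+ mice, a difference of -6.09 with an exact p of 0.0286, the smallest that 35 splits allow, and 0.343 after Benjamini-Hochberg adjustment over 12 types. The share of dSPNs was 38.5% ± 3.12 and 40.0% ± 4.14 (exact p = 0.686). SPNs annotated as unknown made up 0.89% ± 0.54 and 2.13% ± 0.96, and eccentric SPNs 3.02% ± 0.61 and 3.9% ± 0.75 (exact p = 0.143 and 0.171). Whether nuclei moved between annotated SPN types was not tested. Cholinergic interneurons made up 0.48% ± 0.42 and 2.00% ± 0.47 (exact p = 0.0571). Oligodendrocytes were at 9.17% ± 0.70 and 11.5% ± 3.29, astrocytes at 8.02% and 6.23%, and microglia at 1.07% and 2.07%. No type passed the adjustment.

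SPN nuclei of HttQ175/+ mice held fewer UMIs on average, a difference that did not pass the test. Over nuclei of all types the median nucleus held 2553 ± 51.0 UMIs (SD, n = 3) in WT and 2074 ± 323 (SD, n = 4) in HttQ175/+ mice (exact permutation p = 0.0571, 0.171 after adjustment). In dSPNs it held 2769 ± 50.3 and 2167 ± 421 UMIs, and in iSPNs 2541 ± 133 and 1976 ± 372 (exact p = 0.0571 for both). Astrocytes held 1425 ± 74.5 and 1892 ± 414 UMIs and oligodendrocytes 2097 ± 316 and 2137 ± 421 (exact p = 0.171 and 0.943). Mitochondrial UMIs averaged 0.336% and 0.287% of a nucleus (exact p = 0.314). SPN nuclei thinned to 1500 UMIs held 911.5 ± 16.8 genes in WT and 958.8 ± 6.65 in HttQ175/+ mice (exact p = 0.0286, the smallest these splits allow).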

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

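Tests of explanations in this part were all chosen after the results they bear on were seen. Among 132 values over the 4 HttQ175/+ mice (shares of nuclei, depths and levels of named genes), 6 had a mouse far from the other mice by Dixon's gap ratio at its 95% critical value; chance gives about 1 in 20. In dSPNs Ndst3 was low in replicate 3 (4.81 against 5.29 to 5.38 on the log2 scale, ratio 0.835). In iSPNs Cnr1 was low in replicate 3 (6.54 against 7.35 to 7.45, ratio 0.885), Mgat4c in replicate 4 (6.31 against 6.95 to 6.97, ratio 0.970) and Scn4b in replicate 1 (7.29 against 7.57 to 7.62, ratio 0.852). In oligodendrocytes Car2 and Mal were high in replicate 3 (9.83 against 9.0 to 9.07, ratio 0.915, and 9.94 against 9.19 to 9.31, ratio 0.848). The genotype effect on the 36 nuclear genes of oxidative phosphorylation differed between SPN types, with a median difference of -0.244 (iSPN minus dSPN; camera adjusted p = 0.0182, but adjusted p = 0.198 with an estimated correlation).

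Lower genes of the mature cell in glia are the first pattern that could be technical or biological. SPN transcripts were fewer in HttQ175/+ oligodendrocytes but higher as a share of their own lower level in SPNs. The share of UMIs this implies would give other genes a log2 change of -0.346 ± 0.236 (jackknife SE over mice). The median of the myelin list was -1.046 ± 0.274 (gap 0.70 ± 0.084), which argues against dilution by RNA of SPNs as the whole cause. RNA of other cells does not enter this share, so dilution by all sources together was not tested. The SE covers the spread between mice only. In astrocytes the implied change was -0.46 ± 0.177 and the homeostatic list had -0.483 ± 0.233, so dilution and genotype cannot be told apart there; SPN genes in astrocytes followed those in SPNs with a slope of 0.18 ± 0.197 over the 20 identity genes, within 2 SE of 0, but of 0.577 ± 0.215 over 81 genes at least 4-fold higher in SPNs, above it. Less cytoplasmic RNA around oligodendrocyte nuclei stays open, since mitochondrially encoded genes had a median of -0.687 ± 0.313, just over 2 SE, and 5 of 35 splits gave as small a p. A lower myelin programme in HttQ175/+ oligodendrocytes is a hypothesis that these data leave open.

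Fewer UMIs per SPN nucleus may come from the sequencing depth of the library or from the cells. The ratio of SPN to oligodendrocyte UMIs was 1.297 ± 0.202 in WT and 1.005 ± 0.279 in HttQ175/+ mice. Of the 4 HttQ175/+ mice 3 lay below the lowest WT mouse at 1.065. A lower depth of the library would leave this ratio alone only if no filter on UMIs removed nuclei. Nuclei held at least 1128 UMIs, and the filters on nuclei are not given in the sources used here. HttQ175/+ replicate 3 stood at 1.415, and the exact permutation p was 0.200, so depth and genotype cannot be told apart with 7 mice.

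Lower levels of some SPN genes outside SPNs may reflect free RNA of SPNs. Summed SPN markers stood at 4439 and 3368 CPM in oligodendrocytes (1 of 11 called lower) but at 2098 and 2509 CPM in astrocytes. In Sst interneurons these markers stood at 2720 and 1871 CPM, and 0 of 12 identity genes were called (list camera adjusted p = 0.000171, but adjusted p = 0.207 with an estimated correlation). In oligodendrocytes the changes of 26 SPN identity genes followed those in SPNs with a slope of 0.765 ± 0.124, between 0.689 and 0.825 with each mouse left out in turn, as free RNA needs; Scn4b (-1.56 ± 0.31) and Penk (-1.36 ± 0.32), picked after their values were seen, passed in oligodendrocytes (limma adjusted p = 0.0155 and 0.0471). In Sst interneurons the slope over 12 genes was 0.264 ± 0.346, which decides nothing. A first attempt with genes at least 4-fold higher in SPNs had 1 gene in oligodendrocytes and was replaced; it gave 0.577 in astrocytes and 0.621 ± 0.598 over 13 genes in Sst interneurons. A change of these genes in oligodendrocytes and interneurons themselves was not tested apart from free RNA.

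Other ways to split the 7 mice into 3 and 4 give 35 splits. The real split gave the largest counts in dSPNs (349 genes, highest other split 4) and in iSPNs (141, highest other 1). This argues against chance but cannot exclude it, as 1 in 35 is the smallest chance value these splits allow. Every other split mixes genotypes in at least 1 group, which adds spread within groups and can lower its count. The correlation of dSPN and iSPN effects was also highest in the real split (0.634, highest other 0.594). That gap is smaller than the jackknife SE of the correlation, 0.063, so chance is not firmly excluded for its size. The 0.594 came from the split that set HttQ175/+ replicates 1, 2 and 4 against the rest, which keeps part of the genotype effect. The other splits therefore give no clean chance level. Leaving out 1 mouse gave 0.549 to 0.631, from fits of fewer mice. Chance was not excluded for oligodendrocytes (25 genes; highest other 105, so 2 splits as large), where the split that set HttQ175/+ replicates 1, 2 and 4 against the rest called more genes and points to a structure of the samples. It was not excluded for the pairs of list and type (20; highest other 21). In astrocytes, Sst interneurons and the test of the difference the real split called 0 genes and the highest others 3, 1 and 1. Every split is as large as a count of 0, so this comparison can decide nothing there.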

How the results depend on the processing

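Named genes turned sign in 0 of their alternatives; over genes and settings 1615 values kept their side of the threshold, 274 lost it and 7 passed newly. For gene lists 383 values kept their call, 39 lost it, 27 passed newly and 33 turned sign; among other results 247 kept, 40 moved, 3 weakened and 7 turned sign. Pseudocounts, no scaling, recovered UMI sums, voom, thinning to 1500 UMIs, SPNs as 1 class and leaving out HttQ175/+ replicates 2 and 4 were chosen after seeing the data. The cause was not tested, except that equal nuclei, thinning and left-out mice leave less data. DESeq2's Wald test was not run; recovered UMI sums were tested with limma instead of it. A minimum of 30 nuclei was not possible for astrocytes and Sst interneurons, and thinned astrocytes gave no value. In simulated data 41.3% (oligodendrocytes) to 59.0% (astrocytes) of 2-fold changes were recovered. These rates hold for a spread between mice of 0.25 on the log2 scale, which was not matched to each type.

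In dSPNs 168 genes passed with equal nuclei (36 up, 132 down), 226 thinned (61 up, 165 down) and 107 without HttQ175/+ replicates 2 and 4 (14 up, 93 down); in iSPNs 76 passed with equal nuclei and 56 without those mice. In oligodendrocytes 2 passed with no filter, 16 in clean nuclei, 7 with equal nuclei, 48 with a pseudocount of 5 UMIs and 42 with voom; in astrocytes 20 passed with voom, and in interneurons 2 with no filter. The difference between SPN types gave 1 gene, Onecut2, with median-of-ratios factors, clean nuclei, no scaling or UMI sums, 3 (Rpl37, Ryr1, Onecut2) with a pseudocount of 5 UMIs and 1 (Thy1) without HttQ175/+ replicates 2 and 4. Lists passed in 2 pairs with an estimated correlation and 13 with fry; fry turned the sign of cholesterol synthesis (median 0) and oxidative phosphorylation (-0.074) in dSPNs (adjusted p = 0.989). The correlation of SPN effects was 0.900 among genes called in either type, a choice that raises it, and no chance value was computed for that set.

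Leaving out 1 mouse gave 208 to 352 genes in dSPNs (208 without HttQ175/+ replicate 1), 65 to 146 in iSPNs (65 without WT replicate 1), 0 to 11 in astrocytes (11 without HttQ175/+ replicate 3), 1 to 133 in oligodendrocytes (1 without WT replicate 3, 133 without HttQ175/+ replicate 3), 0 to 1 in interneurons and 0 to 3 for the difference. The correlation ran from 0.549 to 0.631. List medians that changed sign or test direction ran, in dSPNs, from -0.099 to 0.279 (DNA repair), -0.083 to 0.080 (cholesterol), -0.211 to -0.004 (ribosomal), -0.147 to 0.211 (heat shock), -0.994 to -0.053 (mitochondrial), -0.180 to 0.191 (oxidative phosphorylation) and 0.009 to 0.150 (p53); in iSPNs from -0.349 to 0.045 (ribosomal), -0.350 to 0.413 (dSPN identity), -0.227 to 0.048 (heat shock), -0.544 to 0.039 (immediate early), -0.293 to 0.089 (oxidative phosphorylation) and -0.335 to 0.085 (p53); in oligodendrocytes from -0.318 to 0.113 (immature), -0.307 to 0.75 (immediate early) and -0.287 to 0.081 (p53); in Sst interneurons from -0.263 to 0.210 (ribosomal), -0.320 to 0.163 (heat shock) and -0.336 to 0.407 (oxidative phosphorylation). Differences of shares ran from -1.819 to 0.038 (Pnoc/Pvalb interneurons), -0.125 to 2.175 (Sst interneurons), -0.221 to 3.212 (dSPNs) and -0.396 to 0.673 (endothelial). Genes enriched in Sst interneurons ran from -0.140 to -0.067, and lost their call without WT replicate 1 (adjusted p = 0.239), HttQ175/+ replicate 1 (0.141) or HttQ175/+ replicate 2 (0.0538). No paired analysis was possible because the labels give no numbers that pair mice across genotypes.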

Other observations

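The values in this part and the choice to look at them came after the data were seen. With dSPNs and iSPNs taken as 1 class, genes enriched in SPNs over the other types had lower medians than those that set 1 SPN type apart, a difference that was not tested: 173 of 200 lay below 0 in dSPNs (median -0.51; 68 fell and 2 rose) and 178 of 200 in iSPNs (median -0.52; 50 fell and 1 rose), with camera adjusted p of 2.02e-35 and 6.27e-34. These lists were chosen on the same samples. Meg3, a long non-coding RNA of the imprinted Dlk1 domain, rose in dSPNs from 22150 ± 1615 to 33340 ± 1387 CPM (0.45 ± 0.09, limma adjusted p = 0.00868) and in iSPNs from 20100 ± 2031 to 30290 ± 1476 CPM (0.47 ± 0.08, adjusted p = 0.00267). In Sst interneurons Meg3 was at 37510 and 39470 CPM (0.04 ± 0.09, adjusted p = 0.922). Ece2, the peptidase next to Vwa5b2 on chromosome 16, rose in dSPNs too (1.22 ± 0.22, adjusted p = 0.00544).

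With the minimum lowered to 8 nuclei per mouse, 3 smaller types could be tested with limma. In eccentric SPNs 1 of 758 genes passed, Pde10a, which fell by 1.46 ± 0.25 (adjusted p = 0.00992; 94 genes at an unadjusted p under 0.05). In oligodendrocyte progenitors 1 of 208 genes passed, Meg3, which rose by 1.46 ± 0.34 (adjusted p = 0.0449; 24 genes unadjusted). SPN markers summed to 2139 ± 430.9 and 2586 ± 477.2 CPM in the same progenitor nuclei, so Meg3 carried in by RNA of neurons was not told apart from their own. In Pnoc/Pvalb interneurons 0 of 833 genes passed, with 52 at an unadjusted p under 0.05. HttQ175/+ replicate 3 stood apart from the other HttQ175/+ mice in oligodendrocytes: SPN identity genes were at 28.4% of their SPN level, against 58.2%, 56.5% and 53.8% in replicates 1, 2 and 4, and the summed oligodendrocyte markers were at 21163 CPM, against a WT mean of 25372 ± 1624 and an HttQ175/+ mean of 13743 ± 5050 CPM. Astrocyte nuclei of HttQ175/+ replicate 1 held 2168 CPM of choroid plexus markers, against 0 to 99.3 CPM in the other mice.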
